A study of Homo sapiens with 9 samples.

How the data were processed

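Total RNA from SKOV3 cells, an established human ovarian tumour cell line, was measured on 9 arrays. Each array held RNA from a separate culture flask, per the labels' protocols, and there were 3 flasks in each of 3 groups: untreated, 50 µM peracetylated N-acetylglucosamine (Ac-GlcNAc) and 50 µM peracetylated 4-deoxy-N-acetylglucosamine (Ac-4-deoxy-GlcNAc), all kept for 3 days. Groups and replicate numbers were taken from the sample titles. No scan date, slide or batch was given in the sources used here, so no batch could be tested.

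The deposited values are on a log2 scale, 1 value per probe set and array, and were made by the authors with RMA in Partek on the hg18 build, per the submitters' processing notes, which give no versions, settings or filters. RMA usually holds background correction, quantile normalization and median polish; whether each step was run is not stated. Array medians lay between 6.58 and 6.65, while the SD over probe sets ran from 1.92 to 2.18, so the arrays did not share one distribution. No scanner files were used here, and signal over background could not be assessed. For arrays, the number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.110.

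The table held 17859 probe sets. Of these, 14413 were paired with 1 gene in the platform annotation, 2405 with several and 1041 with none. No gene was named from a probe set with several genes. Symbols were checked by gene identifier against a RefSeq table of assembly GRCh38.p14, in which 14385 of the 14413 were found. Because that build differs from the authors', its positions were used only to see which genes lie inside others. Where a gene had more than 1 probe set (195 of 14215 genes), the one with the highest mean over the 9 arrays was used.

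The values were analysed as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options). All 9 arrays entered 1 fit with group as the only term and 6 residual degrees of freedom. Each pairwise contrast was tested two-sided with Benjamini-Hochberg adjustment over all probe sets, and a moderated F test asked which probe sets differed among the 3 groups. An adjusted p under 0.05 was called. Shifts of 42 gene lists with 949 entries were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists within a contrast, with an estimated correlation and fry beside it. Of the 949 entries, 763 were measured, and 94 were present only on probe sets naming several genes.

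The tests, groups, lists, rule for named genes and other settings were fixed before the data were examined. Genes were named per comparison as follows. The 10 largest rises and 10 largest falls were taken among called probe sets of 1 gene on which the arrays of the groups did not overlap. Up to 4 called members were taken from each list described, by size, or up to 2 members with the smallest p where none was called. A fixed set of glycan, stress and growth factor genes was given where it passed or bore on a described list. The 10 genes plotted by array, and TAS2R4 and TAS2R39 as examples of taste receptor genes, were chosen after their values were seen. The fall of TAS2R39 with Ac-GlcNAc was named by the rule.

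Other settings fixed with them were the replicate number as a block, cyclic loess, median centring, filters at the 25th and 50th percentile of mean level, eBayes with trend and robust options, array weights, the 6 compared arrays alone, a 1.5-fold minimum, other list tests and leaving out each array. After the ranges of the arrays were seen, 3 further settings were added: quantile normalization, the SD of each array as a covariate, and leaving out untreated replicate 2 with Ac-4-deoxy-GlcNAc replicate 1.

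The fit was tested on simulated arrays of 17859 probe sets with the observed spread, in which 200 were changed. For Ac-GlcNAc against untreated it recovered 67.2% of 1.5-fold changes and 98.5% of 2-fold changes. For Ac-4-deoxy-GlcNAc against untreated the shares were 64.2% and 92.5%, and for Ac-4-deoxy-GlcNAc against Ac-GlcNAc 61.2% and 91.0%. Unchanged probe sets called were 11, 13 and 10. Each probe set had a spread pooled over the groups and independent noise, without shifts of whole arrays. The shares of the comparisons therefore differ only by the random draw.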

Results

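The series asked how gene expression in SKOV3 ovarian tumour cells responds to a cell-permeable, acetylated form of the amino sugar GlcNAc and to an analog lacking the hydroxyl group at carbon 4. Expression was measured on 9 arrays, 3 per group, from untreated cells and from cells given 50 µM of either compound for 3 days. Median log2 values per array lay between 6.58 and 6.65. Untreated replicate 2 had the narrowest range of values, with an SD over probe sets of 1.92 against 2.07 to 2.18 on the other arrays, and a mean correlation of 0.987 with them. Across the 3 groups, 1493 of 17859 probe sets differed at an adjusted p under 0.05. This count was 2905 with array weights, 2533 and 942 without untreated replicate 1 and 2, 854, 722 and 784 without Ac-GlcNAc replicate 1, 2 and 3, and 660 and 490 without Ac-4-deoxy-GlcNAc replicate 1 and 3.

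Against untreated cells, Ac-4-deoxy-GlcNAc lowered AMTN, which encodes the enamel protein amelotin, by the most among named genes. Its log2 level was 9.02 ± 0.18 (SD, n = 3) against 11.24 ± 0.18 in untreated cells, a 4.67-fold difference (adjusted p = 6.14e-07). NMUR2, a neuromedin U receptor, fell by 1.67 on the log2 scale (SE 0.10), and VSNL1, HES1 and FOXS1 fell by 1.45, 1.36 and 1.32. ITGB4, the integrin beta 4 subunit, and MMP1, interstitial collagenase, fell by 1.09 each (SE 0.09 and 0.13). Among the rises, CYP24A1, the vitamin D 24-hydroxylase, was 2.63-fold higher (log2 1.39, SE 0.12, adjusted p = 6.03e-05). SYNE2, LRRN4 and TENM1 rose by 1.21, 1.11 and 1.06, and PHGDH, the first enzyme of serine synthesis, by 1.10 (SE 0.09). CHORDC1 rose by 1.77, with an SD of 0.70 among the untreated arrays, and its symbol also stands on a probe set shared with other genes. CHORDC1 was also called higher with Ac-GlcNAc against the same untreated arrays, but in only 3 of the 6 fits with 1 array left out (log2 0.94 to 1.56).

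In total, 1968 probe sets changed with Ac-4-deoxy-GlcNAc, 960 higher and 1008 lower, and 478 of them by at least 1.5-fold. The balance turned with the setting: 1018 were higher and 826 lower with median centring, 1186 and 1079 with cyclic loess, and 1128 and 553 above the median level. On 1940 of the 1968 the 3 arrays of each group did not overlap. That held for 32.1% of all probe sets, and for 32.3% with Ac-GlcNAc, where the mean over all splits into 3 and 3 arrays is 10%. Probe sets of an array can shift together, so a single split can lie far from that mean without an effect. The share under other splits was not computed, so the excess cannot be read as a response. The count depended on single arrays: it was 3076 without untreated replicate 1, 1003 without untreated replicate 2, 890 without Ac-4-deoxy-GlcNAc replicate 1 and 604 without Ac-4-deoxy-GlcNAc replicate 3. It was 730 without untreated replicate 2 and Ac-4-deoxy-GlcNAc replicate 1 together, 818 on the 6 compared arrays alone and 596 with the SD of each array as a covariate. Of 83 named genes called, counting each once, 55 stayed called in each of the 6 fits with 1 array left out. With array weights 1916 probe sets were called, against 1760 with Ac-GlcNAc. At an unadjusted p under 0.05 the counts were 5579 and 4719. Array weights closed most of the gap between 1968 and the 79 called with Ac-GlcNAc. They were estimated from the same arrays, and ran from 0.241 on untreated replicate 2 to 2.89 on Ac-GlcNAc replicate 1. Without untreated replicate 1 the counts were 3076 and 1359. The gap stayed wide with cyclic loess (2265 and 47), quantile normalization (2204 and 36) and without untreated replicate 2 (1003 and 23).

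Of 16 measured genes of cholesterol synthesis, 10 were higher and 0 lower with Ac-4-deoxy-GlcNAc, and 10 higher and 1 lower when adjusted over the list alone. They included HMGCS1 (log2 0.73, SE 0.09), which makes the precursor of mevalonate, INSIG1 (0.71, SE 0.12), DHCR7 (0.70, SE 0.12) and MVK (0.69, SE 0.13). The list had a camera adjusted p of 1.79e-08, and an adjusted p = 0.152 with an estimated correlation. Of 15 genes of fatty acid synthesis and desaturation, 5 were higher and 0 lower (6 and 0 adjusted over the list alone), with SCD, the stearoyl-CoA desaturase, at 0.71 (SE 0.10) and ACSS2 at 0.62 (SE 0.11). Its adjusted p was 1.14e-05, and adjusted p = 0.257 with an estimated correlation.

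With Ac-4-deoxy-GlcNAc, part of the stress response and amino acid genes were higher. Of 29 genes of the ATF4 and amino acid response, 9 were higher and 0 lower (13 and 0 adjusted over the list alone), among them PHGDH, WARS1 (log2 0.76, SE 0.11), PSAT1 (0.71, SE 0.12) and PCK2 (0.65, SE 0.10). The list gave an adjusted p of 1.5e-09, and adjusted p = 0.179 with an estimated correlation. DDIT3, a stress-induced transcription factor, had a log2 difference of 0.42 (adjusted p = 0.0611), which did not pass. Of 27 genes for the unfolded protein response, chaperones and degradation of misfolded proteins, 8 were higher and 1 lower (11 and 1 adjusted over the list alone), with DNAJC3 at 0.80 (SE 0.13), HERPUD1 at 0.71 (SE 0.10), HYOU1 at 0.67 (SE 0.10) and the chaperone HSPA5 at 0.55 (SE 0.11), which was not called without Ac-4-deoxy-GlcNAc replicate 3 (adjusted p = 0.0544). That list gave an adjusted p of 0.00014, and adjusted p = 0.257 with an estimated correlation. Of 15 genes of the NRF2 oxidative stress response, 3 were higher and 0 lower (6 and 0 adjusted over the list alone), with TXNRD1, a thioredoxin reductase, at 0.70 (SE 0.10). TXNRD1 stayed called in each of the 6 fits with 1 array left out, while ABCC2 was called in 1 and AKR1C3 in 2. The NRF2 list had an adjusted p of 0.00445, with adjusted p = 0.257 with an estimated correlation and 0.093 after cyclic loess. The DNA replication list was called higher at 0.0327, with 1 of 25 members higher (0 adjusted over the list alone), and had adjusted p = 0.765 with an estimated correlation, 0.446 after cyclic loess, 0.378 without untreated replicate 2 and 0.185 without Ac-4-deoxy-GlcNAc replicate 3.

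Both enzymes that cycle O-GlcNAc on proteins rose with Ac-4-deoxy-GlcNAc. OGA, which removes the sugar, was 2.01-fold higher (log2 1.01, SE 0.14, adjusted p = 0.00118), and OGT, which adds it, was 1.49-fold higher (log2 0.58, SE 0.10, adjusted p = 0.00344). The list of 3 measured genes had 2 higher (also 2 adjusted over the list alone), with a camera adjusted p of 0.00554, and adjusted p = 0.179 with an estimated correlation. Both genes stayed called in each fit with 1 array left out. TXNIP, a glucose-responsive gene, fell by 0.47 (SE 0.10, adjusted p = 0.0142), and was not called without Ac-4-deoxy-GlcNAc replicate 3 (adjusted p = 0.0732).

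Of 34 measured extracellular matrix genes, 10 were lower, 1 higher and 23 not called with Ac-4-deoxy-GlcNAc (12 lower and 1 higher adjusted over the list alone): the collagen chains COL1A1 and COL1A2 fell by 0.92 and 0.85 (SE 0.09 and 0.10), SPARC by 0.80 (SE 0.09) and BGN by 0.61 (SE 0.10). The list gave an adjusted p of 0.00243, and adjusted p = 0.152 with an estimated correlation. COL1A2 shares its symbol with a probe set naming several genes. Of 10 fibroblast markers, 5 were lower and 0 higher (7 and 0 adjusted over the list alone), including POSTN (-0.60, SE 0.12). This list shares the entries COL1A1, COL1A2, COL3A1, DCN and LUM with the matrix list, so the 2 calls are not separate results. It was included only to check for foreign cells in a cell line. The list had a camera adjusted p of 0.00141, and adjusted p = 0.257 with an estimated correlation. Its mean level was low, at 5.52, and cyclic loess took its median log2 change from -0.357 to -0.2. Of 21 TGF-beta response genes, 9 were lower and 1 higher (10 and 2 adjusted over the list alone), such as PMEPA1 (-0.72, SE 0.11), JUNB (-0.60, SE 0.12) and SMAD7 (-0.54, SE 0.11). As a list these had a camera adjusted p = 0.0819, which did not pass, 0.682 with an estimated correlation and 0.00168 after cyclic loess.

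**Figure D1:**
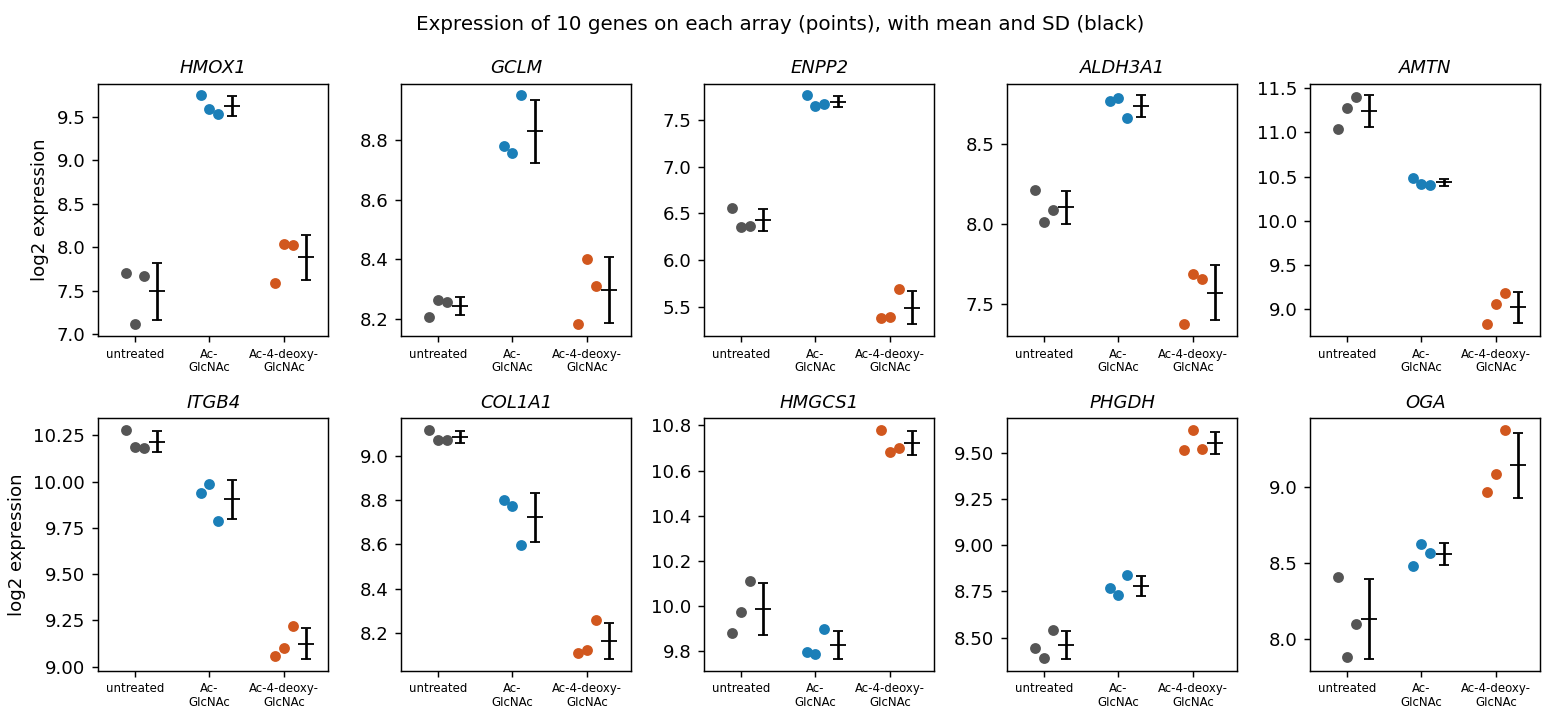
Log2 expression of 10 genes on each array (points, 3 per group), with the mean and SD in black; the axes differ between genes and do not start at 0. AMTN lies at a mean of 11.24 in untreated cells, 10.44 with Ac-GlcNAc and 9.02 with Ac-4-deoxy-GlcNAc, while HMOX1 is high with Ac-GlcNAc, at 9.63 against 7.49 untreated.

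With Ac-GlcNAc, the largest rise among named genes was in HMOX1, heme oxygenase 1. Its log2 level was 9.63 ± 0.11 (SD, n = 3) against 7.49 ± 0.33 untreated, a 4.38-fold difference (adjusted p = 6.14e-05). ENPP2, which encodes autotaxin, was 2.42-fold higher (log2 1.27, SE 0.11, adjusted p = 0.000152). The bile and drug transporter ABCC2 rose by 0.82 (SE 0.10, adjusted p = 0.00548), SLC51B by 0.95 (SE 0.14) and AKR1C3, an aldo-keto reductase, by 0.93 (SE 0.11). AKR1C3 has close paralogs, and its symbol also stands on a probe set naming several genes. AMTN fell by 0.80 (SE 0.12, adjusted p = 0.019), PIN4 by 1.25 (SE 0.16) and TAS2R39 by 1.28 (SE 0.23), the last at a low mean level of 4.02.

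Of 15 measured genes of the NRF2 oxidative stress response, 6 were higher and 0 lower (11 and 0 adjusted over the list alone): HMOX1, AKR1C3, ABCC2 and FTL, the ferritin light chain (log2 0.61, SE 0.12), were the largest. The list gave a camera adjusted p of 8.48e-12, and adjusted p = 0.0722 with an estimated correlation. Of the 10 other lists that camera called, none held a member called over all probe sets. Among those called higher, the ATF4 and amino acid list (9 of 29 higher adjusted over the list alone) had an adjusted p of 3.58e-05, and adjusted p = 0.463 with an estimated correlation. The heat shock list (6 of 11 higher adjusted over the list alone) had 0.00587, and adjusted p = 0.197 with an estimated correlation. Fibroblast markers (6 of 10 lower adjusted over the list alone) were called lower at 0.00138, and had adjusted p = 0.372 with an estimated correlation. Extracellular matrix genes (3 of 34 lower and 1 higher adjusted over the list alone) were called lower at 0.00937, and had adjusted p = 0.197 with an estimated correlation and 0.0598 without untreated replicate 3. Cyclic loess ended 7 of the 11 list calls, leaving those of the NRF2, ATF4, fibroblast and extracellular matrix lists. Their median log2 changes went from 0.387 to 0.269, 0.164 to 0.065, -0.328 to -0.153 and -0.166 to -0.138. Of the 11 calls, 5 ended in at least 1 of the 6 fits with 1 array left out. The fatty acid and unfolded protein response lists were each called in 3 fits, mitosis in 4, and DNA replication and extracellular matrix each in 5.

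In all, 79 probe sets changed with Ac-GlcNAc, 37 higher and 42 lower, against 4719 at an unadjusted p under 0.05. The count was 1760 with array weights (904 higher, 856 lower), 141 with trend and robust options, 47 with cyclic loess and 48 on the 6 compared arrays. Median centring gave 19 higher and 13 lower, a share of 59.4% higher against 46.8%. That share was 81.8% above the median level (126 higher, 28 lower) and 21.8% without untreated replicate 3 (54 higher, 194 lower). With the SD of each array as a covariate, 2 probe sets were called, those of HMOX1 and ENPP2. That SD ran from 2.14 to 2.18 on Ac-GlcNAc arrays and from 1.92 to 2.08 on untreated arrays. The covariate thus takes up part of the group difference, and a call lost with it does not show an artefact. The count was 1359, 23 and 248 without untreated replicate 1, 2 and 3, and 9, 7 and 4 without Ac-GlcNAc replicate 1, 2 and 3. Of 21 named genes called, HMOX1, ENPP2 and ABCC2 stayed called in each of those 6 fits, and the other 18 lost their call in at least 1.

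The structural comparison at the same dose and time showed differences between the compounds. Ac-4-deoxy-GlcNAc and Ac-GlcNAc differed at 425 probe sets, 160 higher and 265 lower with the 4-deoxy compound. On 21.2% of probe sets the arrays did not overlap, where 10% is the mean over all splits into 3 and 3 and other splits were not computed. The split was 173 higher and 205 lower with median centring, 263 and 330 with cyclic loess, 143 and 364 above the median level, and 235 and 258 without Ac-4-deoxy-GlcNAc replicate 2. ENPP2 was 4.65-fold lower with Ac-4-deoxy-GlcNAc (log2 -2.22, SE 0.11, adjusted p = 2.5e-07), HMOX1 3.34-fold lower (-1.74, SE 0.16), AMTN 2.68-fold lower (-1.42, SE 0.12) and ALDH3A1, an aldehyde dehydrogenase, 2.25-fold lower (-1.17, SE 0.11). LRRN4 was 2.18-fold higher (log2 1.12, SE 0.11), FGFBP1 2.04-fold and CYP24A1 1.93-fold. The count of 425 was 1187 with array weights, 148, 165 and 159 without Ac-GlcNAc replicate 1, 2 and 3, 141 without Ac-4-deoxy-GlcNAc replicate 1 and 199 without Ac-4-deoxy-GlcNAc replicate 3. Of 47 named genes called, 21 stayed called in each of the 6 fits with 1 array left out.

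Cholesterol synthesis genes were higher with Ac-4-deoxy-GlcNAc than with Ac-GlcNAc in 9 of 16 cases and lower in 0 (12 and 0 adjusted over the list alone), with HMGCS1 at 0.89 (SE 0.09), INSIG1 at 0.76 (SE 0.12) and MVD at 0.65 (SE 0.10). The list gave an adjusted p of 8.81e-13, and adjusted p = 0.106 with an estimated correlation. NRF2 genes were lower in 5 of 15 cases and higher in 0 (6 and 0 adjusted over the list alone), including GCLM, a subunit of the glutathione synthesis enzyme (-0.53, SE 0.10; not called without Ac-4-deoxy-GlcNAc replicate 1 or Ac-GlcNAc replicate 3), at an adjusted p of 1.3e-06, and adjusted p = 0.158 with an estimated correlation. TGF-beta response genes were lower in 7 of 21 cases and higher in 0 (12 and 2 adjusted over the list alone), such as ID3 (-0.81, SE 0.13) and ID2 (-0.69, SE 0.11), whose symbol also stands on a shared probe set, at an adjusted p of 6.69e-06, and adjusted p = 0.297 with an estimated correlation. PHGDH was higher by 0.78 (SE 0.09) and OGA by 0.58 (SE 0.14, adjusted p = 0.0405), and OGA was called in 0 of the 6 fits with 1 array left out. Between the compounds 7 other lists were called, with at most 3 members called in any (at most 8 adjusted over the list alone), and had adjusted p = 0.297 to 0.407 with an estimated correlation. Of these, the MondoA list was called in 2 of the 6 fits with 1 array left out, and the unfolded protein response and mesenchymal lists in 5. OGT differed by 0.36 (95% interval 0.16 to 0.57, adjusted p = 0.067) and DDIT3 by 0.01 (-0.28 to 0.31, adjusted p = 0.993), neither of which passed. NDST1, which starts the sulfation of heparan sulfate, differed by 0.01 (-0.18 to 0.20) and UAP1, which makes UDP-GlcNAc, by -0.03 (-0.27 to 0.22).

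**Figure D2:**
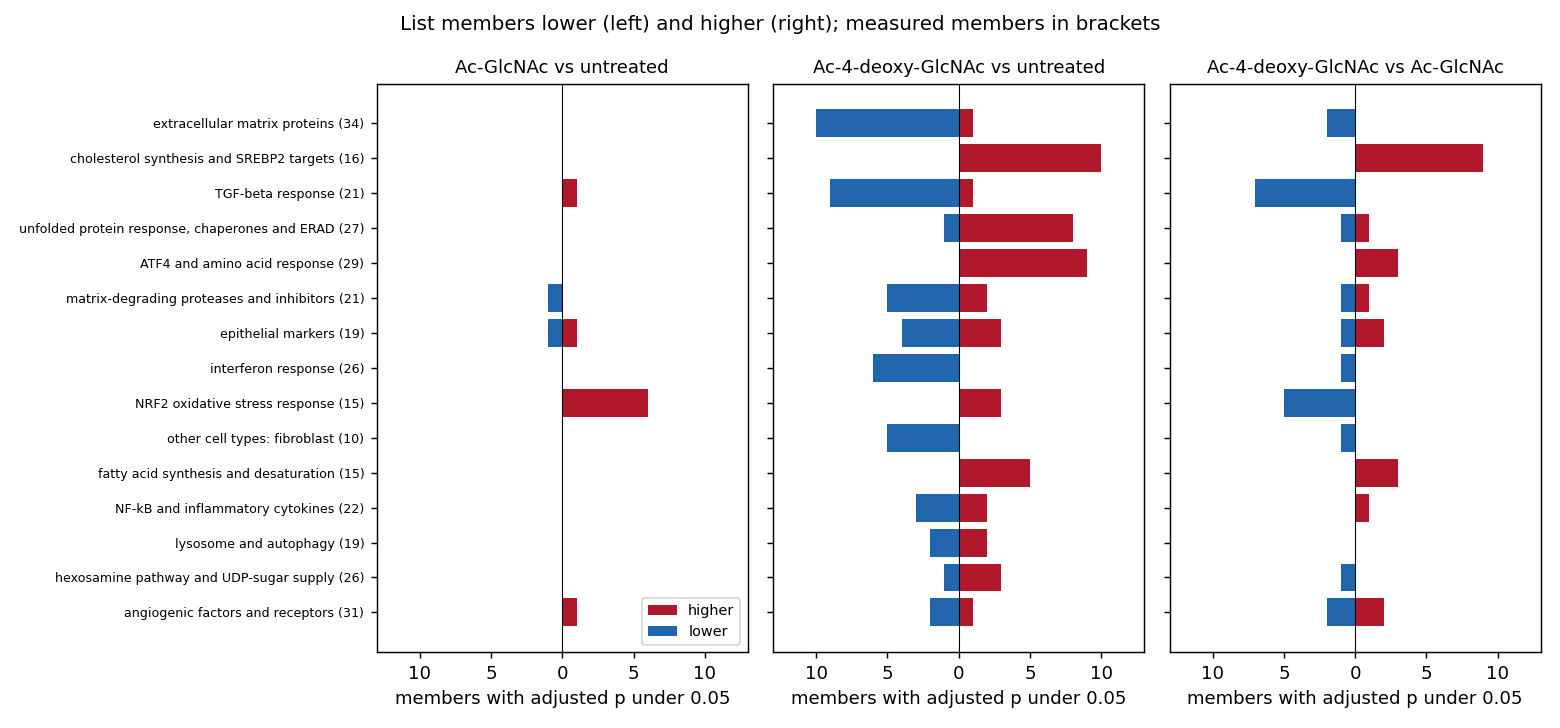
Members of gene lists with an adjusted p under 0.05, lower to the left and higher to the right of 0, in each comparison, for lists with at least 4 such members in 1 comparison; measured members stand in brackets. With Ac-4-deoxy-GlcNAc, 10 of 16 cholesterol synthesis genes are higher, while with Ac-GlcNAc 6 of 15 NRF2 genes are higher.

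Genes for the supply of the sugar and for heparan sulfate are set here beside the 1968 of 17859 probe sets called with Ac-4-deoxy-GlcNAc. Of 26 genes of the hexosamine pathway and UDP-sugar supply, 3 were higher and 1 lower with Ac-4-deoxy-GlcNAc against untreated (the same counts adjusted over the list alone): GNE (0.44, SE 0.09), NANS (0.41, SE 0.12) and SLC35D2 (0.39, SE 0.10) rose, and NAGK, the kinase that phosphorylates GlcNAc, fell by 0.51 (SE 0.10). NANS and SLC35D2 were called in 1 and 2 of the 6 fits with 1 array left out, and the list had an adjusted p of 0.141. With Ac-GlcNAc 0 members were called, and 3 higher when adjusted over the list alone, while the list had an adjusted p of 0.00937, and adjusted p = 0.601 with an estimated correlation. NAGK was also lower with Ac-4-deoxy-GlcNAc than with Ac-GlcNAc (-0.41, SE 0.10, adjusted p = 0.0451), and was called in 1 of the 6 fits with 1 array left out. GFPT1, which starts the pathway, differed from untreated by 0.08 (95% interval -0.14 to 0.30) with Ac-GlcNAc and by -0.03 (-0.25 to 0.19) with Ac-4-deoxy-GlcNAc. Of 27 genes of heparan sulfate synthesis, 3 were lower and 0 higher with Ac-4-deoxy-GlcNAc against untreated (4 and 1 adjusted over the list alone). EXTL2, a glycosyltransferase of the linkage region, fell by 0.78 (SE 0.15, adjusted p = 0.00748), B3GALT6 by 0.38 and SLC35B3 by 0.36; the last 2 were called in 2 and 1 of the 6 fits with 1 array left out. The list itself had a camera adjusted p of 0.127, with 0.497 with an estimated correlation and 0.0473 after cyclic loess. EXT1 differed by 0.28 (95% interval 0.08 to 0.48, adjusted p = 0.0637) and did not pass.

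Over all probe sets, the 2 compounds' log2 changes against untreated correlated at r = 0.701 across genes, which are not independent replicates. Both comparisons use the same 3 untreated arrays. In 100 simulations without effects r was 0.644. The covariance was 0.0428 against a simulated 0.0125, a difference of 0.0303. Of 63 probe sets called with both compounds, 22 were higher in both and 39 lower in both, where independent lists give 1.99 and 2.37. The other 2 moved in opposite directions. In 20 simulations without effects, the means higher and lower in both were 0.2 and 0.15. With no effect few probe sets can be called at all, so these means are no baseline for the shared controls. Part of the excess in r, covariance and overlap may come from the shared controls, which are too few to split. The simulations drew every probe set and array independently, so they held no shift common to many probe sets of an untreated array. The excess in r and covariance over the simulations therefore cannot be read as an effect shared by the compounds. The correlation was 0.784 without untreated replicate 1, 0.572 without untreated replicate 2 and 0.611 without Ac-4-deoxy-GlcNAc replicate 3. After cyclic loess it was 0.646, near the simulated 0.644, which was drawn for the values without loess.

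**Figure D3:**
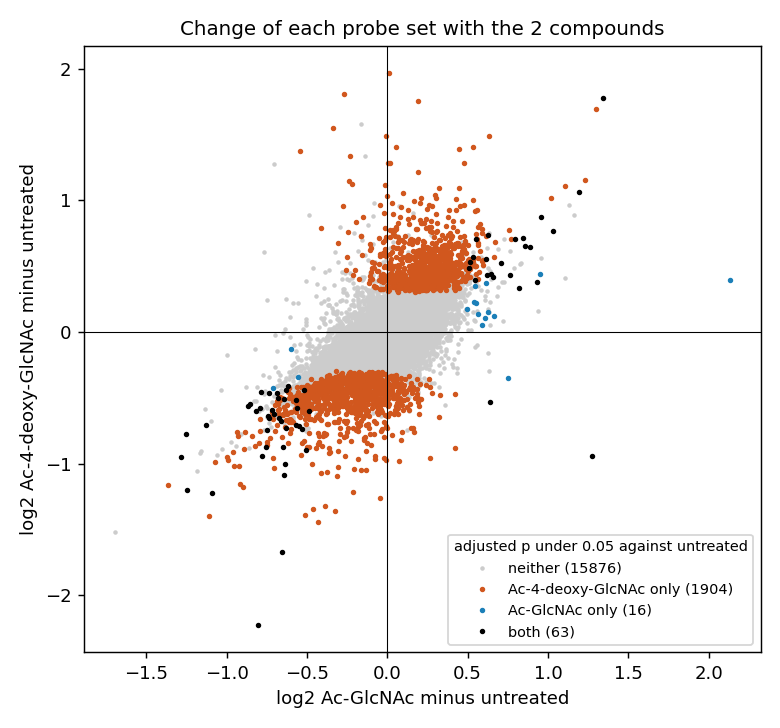
Log2 change of each of 17859 probe sets with Ac-GlcNAc (horizontal) and with Ac-4-deoxy-GlcNAc (vertical), both against untreated; colours mark an adjusted p under 0.05. The 63 probe sets called with both compounds include 22 higher in both and 39 lower in both, and 2 lie in opposite quadrants.

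Change also followed expression level. In the lowest decile of mean level the median log2 change against untreated was -0.23 with Ac-GlcNAc and -0.19 with Ac-4-deoxy-GlcNAc, and in the highest decile 0.11 and 0.06. Without untreated replicate 2 these were -0.13 and -0.09, and 0.07 and 0.02. Between the compounds the medians were 0.04 and -0.05. The lists called at the preset correlation are read with this limit: none was called in any of the 3 comparisons with an estimated correlation, at lowest adjusted p of 0.0722, 0.152 and 0.106, and other splits of the same arrays into 3 and 3 called up to 9, 14 and 7 lists.

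**Figure D4:**
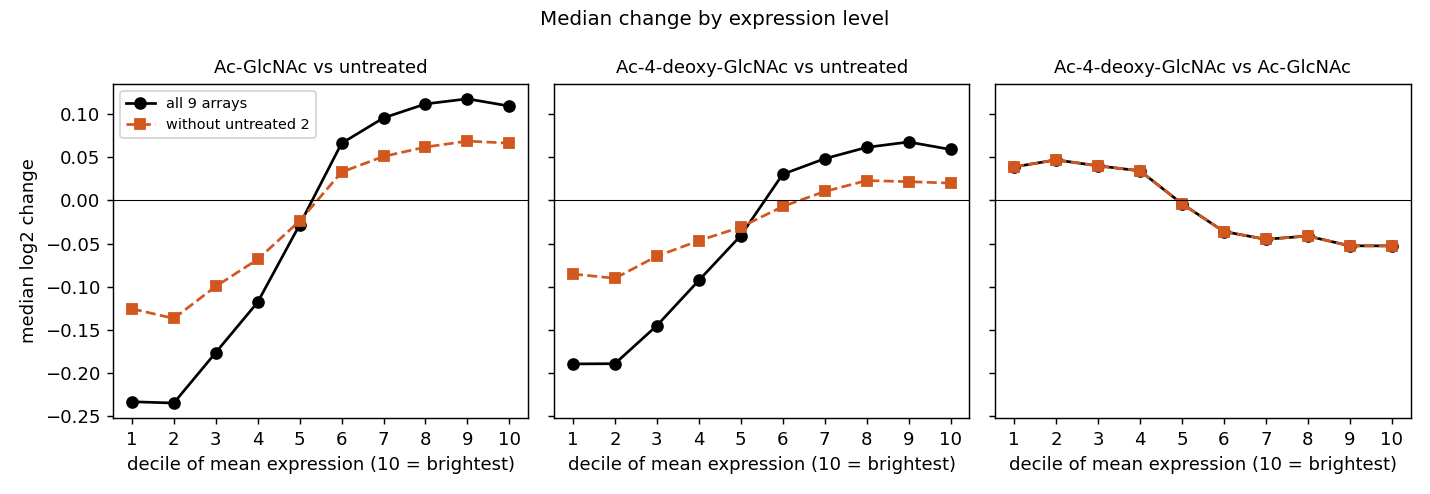
Median log2 change in each decile of mean expression (10 is the brightest), for each comparison, with all 9 arrays (circles) and without untreated replicate 2 (squares). The lowest decile moves from -0.23 to -0.13 with Ac-GlcNAc when that array is left out.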

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

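The tests on the NRF2 list and on the range of the arrays, and the SD covariate, were chosen after the results were seen, while the counts of other splits were planned.

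ENPP2 and ALDH3A1 were the 2 genes called against untreated with both compounds in opposite directions. ENPP2 was at a log2 change of 1.27 (SE 0.11) with Ac-GlcNAc and -0.94 (SE 0.11) with Ac-4-deoxy-GlcNAc, and was called in 6 of 6 fits with 1 array left out for each. ALDH3A1 was at 0.64 (SE 0.11, adjusted p = 0.0269) and -0.53 (SE 0.11, adjusted p = 0.00862). Its call with Ac-4-deoxy-GlcNAc held in 6 of 6 such fits and that with Ac-GlcNAc in 2 of 6, ending without untreated replicate 2 (0.0701) or Ac-GlcNAc replicate 1, 2 or 3 (0.0868, 0.137 and 0.11), and with the SD of each array as a covariate (0.50, adjusted p = 1). ENPP2 was lower with Ac-4-deoxy-GlcNAc than with Ac-GlcNAc by a log2 difference of -2.22 (adjusted p = 2.5e-07), and ALDH3A1 by -1.17 (adjusted p = 0.000134). As both genes were picked for opposite calls against the same untreated arrays, these differences add no independent support.

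The NRF2 list was higher with Ac-GlcNAc than in untreated cells. An intensity-dependent trend between arrays as the whole cause is argued against by its adjusted p of 4.03e-10 after cyclic loess. A single array as the cause is argued against by an adjusted p of at most 2.09e-08 when each of the 6 arrays was left out. Sequence shared between AKR1C3, the only measured aldo-keto reductase of the list, and its paralogs is argued against as the whole cause by an adjusted p of 3.39e-10 over the other 14 of 15 members, while it stays open for AKR1C3 itself. The mean deviation of the list's members was 0.27 to 0.31 on the Ac-GlcNAc arrays, -0.32 to -0.20 on untreated arrays and -0.10 to 0.01 with Ac-4-deoxy-GlcNAc. These p-values use the preset correlation and the estimated one gave 0.0722, so an effect of the compound stays open.

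Dim probe sets were lower and bright ones higher on treated than on untreated arrays. For Ac-GlcNAc, the narrow range of untreated replicate 2 alone is argued against: the gap between the highest and lowest decile on each Ac-GlcNAc array was at least 0.129 above the larger gap of untreated replicates 1 and 3. For Ac-4-deoxy-GlcNAc the same measure was -0.00341, as its replicate 1 had a gap of 6.31 against 6.313 on untreated replicate 3. The mean difference was still 0.109, so the range of untreated replicate 2 and the treatment cannot be told apart. For both compounds only 2 other untreated arrays remain. Probe-level normalization could not be examined here.

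Of the 10 ways to split the 6 compared arrays, 1, the real one, gave as many changed probe sets in each comparison: 79, 1968 and 425 against a highest of 0 in the others. The lists differ in this respect. The real split called 11, 9 and 10 lists, and the highest of the other splits called 9, 14 and 7, so that 1, 2 and 1 of the 10 splits called as many. With 10 splits no share under 0.05 can be reached. Over all 3 groups, 1 of 100 drawn splits of the 9 arrays, the real one, gave as many as 1493 probe sets. The highest other gave 407, which makes chance alone an unlikely source of that count. The test takes the arrays as exchangeable, and a batch that runs with the groups could not be tested.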

How the results depend on the processing

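Quantile normalization, the SD of each array as a covariate and leaving out untreated replicate 2 with Ac-4-deoxy-GlcNAc replicate 1 were chosen after the data were seen. Of 151 called results of genes named by the rule, 120 stayed called with 9 arrays under each of the settings fixed beforehand for single genes, which were the replicate block, cyclic loess, median centring, trend and robust options and the mean of all probe sets of a gene. The other 31 lost the call under at least 1, and 0 turned direction under any setting run for single genes. With the SD covariate 58 of the 151 lost the call, without the 2 arrays 38 and with quantile normalization 16. As the SD itself differs between untreated and Ac-GlcNAc arrays, losses and turns with that covariate cannot tell an artefact from the compound. Array weights and minimum levels were not run for single genes. Signal over background was not used here, so its limit on dim genes is unknown. Except where fewer arrays or a size minimum explain a lower count, the cause was not tested.

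For Ac-GlcNAc against untreated, 79 probe sets became 47 with cyclic loess, 32 with median centring, 154 above the median level, 141 with trend and robust options, 1760 with array weights, 48 on the 6 compared arrays, 36 with quantile normalization, 2 with the SD covariate and 49 without the 2 arrays, and 4 to 1359 without single arrays. The 11 lists became 4 with cyclic loess, 4 above the 25th percentile, 0 with an estimated correlation, 6 with fry, 4 with quantile normalization, 7 with the SD covariate, 6 without the 2 arrays and 7 to 16 without single arrays. For Ac-4-deoxy-GlcNAc against untreated, 1968 became 818 on the 6 arrays, 478 at 1.5-fold, 596 with the SD covariate, 730 without the 2 arrays and 604 to 3076 without single arrays, and the 9 lists 0 with an estimated correlation, 14 with fry and 9 to 12 without single arrays. Between the compounds, 425 became 1187 with array weights, 189 at 1.5-fold and 141 to 493 without single arrays, and the 10 lists 0 with an estimated correlation and 8 to 11 without single arrays. Among the 3 groups, 1493 became 2905 with array weights, 759 with the SD covariate, 567 without the 2 arrays and 490 to 2533 without single arrays. The correlation of the compounds ran from 0.572 to 0.784 without single arrays.

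The replicate numbers did not clearly pair the arrays: 3 of 9 same-numbered pairs correlated above 0.1 (range -0.245 to 0.369), and 3 of 9 arrays correlated best with their own number. Untreated and Ac-GlcNAc pairs were at 0.142, 0.050 and 0.369, so a pairing there stays open. Untreated and Ac-4-deoxy-GlcNAc pairs were at -0.245, 0.048 and 0.140, and all pairs between the compounds were negative. With the number as a block, 324 probe sets were called for Ac-GlcNAc against untreated (96 higher, 228 lower, 29.6% higher), 2207 for Ac-4-deoxy-GlcNAc against untreated and 432 between the compounds.

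Some differences that were not called turned sign. For Ac-GlcNAc against untreated, cyclic loess gave log2 values of -0.011 for EXT1, -0.032 for GFPT1, -0.036 for UAP1 and -0.10 for SDC1, quantile normalization -0.0075, -0.042, -0.038 and -0.098, median centring -0.012 for SDC1, and the SD covariate 0.027 for EMCN, -0.074 for UAP1 and -0.071 for SDC1. UAP1 with Ac-4-deoxy-GlcNAc against untreated was -0.014, -0.017 and -0.055 with loess, quantile normalization and the SD covariate. Between the compounds UAP1 was 0.022, 0.021 and 0.019 under those, 0.0030 with median centring and 0.038 without the 2 arrays. Without single arrays, UAP1 ran from -0.040 to 0.16 and SDC1 from -0.048 to 0.084 for Ac-GlcNAc against untreated. For Ac-4-deoxy-GlcNAc against untreated GFPT1 ran from -0.063 to 0.043, GLCE from -0.10 to 0.017, NDST1 from -0.057 to 0.011 and SDC4 from -0.10 to 0.027. Between the compounds DDIT3 ran from -0.090 to 0.081, NDST1 from -0.0090 to 0.044 and UAP1 from -0.11 to 0.089.

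Lists that turned direction are given by adjusted p. With cyclic loess these were the endothelial (0.893) and leukocyte (0.905) lists for Ac-GlcNAc and the endothelial list (0.446) for Ac-4-deoxy-GlcNAc, both against untreated, and with quantile normalization the same at 0.820, 0.950 and 0.429. Above the 25th percentile it was the endothelial list for Ac-4-deoxy-GlcNAc (0.897), and without the 2 arrays the NF-kB list (0.894). With the SD covariate, 4 called lists turned: fatty acid synthesis (0.880), DNA replication (0.284) and mitosis (0.284) for Ac-GlcNAc, and DNA replication (0.981) for Ac-4-deoxy-GlcNAc. Uncalled lists that turned there were endothelial (0.795) and leukocyte (0.491) for Ac-GlcNAc, and NF-kB (0.981) and endothelial (0.451) for Ac-4-deoxy-GlcNAc. Without single arrays, lists that turned for Ac-4-deoxy-GlcNAc against untreated ran from 0.428 to 0.976 (NF-kB), 0.747 to 0.981 (epithelial) and 0.686 to 0.965 (endothelial), and between the compounds from 0.607 to 0.979 (angiogenic) and 0.473 to 0.977 (leukocyte).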

Other observations

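The tests of dim genes inside other genes were chosen after the result was seen.

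Several lists had members that moved with Ac-4-deoxy-GlcNAc without the list as a whole being called. Of 26 interferon response genes, 6 were lower and 0 higher (6 and 1 adjusted over the list alone), with IFITM1 at a log2 change of -1.02 (SE 0.13) and IFI44L at -0.63 (SE 0.11). The list had an adjusted p of 0.198. Of 21 matrix-degrading proteases and inhibitors, 5 were lower and 2 higher (5 and 3 adjusted over the list alone): besides MMP1, MMP7 (-0.87, SE 0.11) and MMP10 (-0.70, SE 0.10) fell, and ADAMTS1 rose by 0.53 (SE 0.10), at a list adjusted p of 0.314.

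Of 22 NF-kB and cytokine genes, 2 were higher and 3 lower (the same adjusted over the list alone). IL6 was at 0.64 (SE 0.13) on its brighter probe set and at 0.034 on its other one, and IL1A rose by 0.50 (SE 0.12), while CXCL6 was at -0.63 and CCL20 at -0.54, both at low mean levels. Of 19 epithelial markers 3 were higher and 4 lower (3 and 4 adjusted over the list alone). MUC1 was at -0.72 (SE 0.09) and KRT19 at -0.49 (SE 0.10), and the cadherin CDH1 rose by 0.45 (SE 0.10). Of these, CCL20 and CDH1 were not called without Ac-4-deoxy-GlcNAc replicate 3, CXCL6 also without untreated replicate 2, IL1A without Ac-4-deoxy-GlcNAc replicate 1 or 3, and KRT19 without Ac-4-deoxy-GlcNAc replicate 1.

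At 0.5 above the mean of the other 8 arrays, 877 of 3267 dim genes lying in no other gene were high on untreated replicate 2, 33 on Ac-4-deoxy-GlcNAc replicate 1 and 1 to 17 on each other array. Whether dim genes lying inside bright genes were high more often was tested with Fisher's exact test: on untreated replicate 2 no difference was called (8 of 37, adjusted p = 1), and on Ac-4-deoxy-GlcNAc replicate 1 the outcome depended on the definition of high. There 4 of 37 were high by that definition, and at 0.5 above each of the others, 2 of 37 against 10 of 3267. Adjusted over the 9 arrays, p was 0.00608 and 0.0676, and 0.00394 and 0.0379 without taste receptor genes, none of them among the 37, of which some were high there (TAS2R4 at 6.91 against a mean of 3.77) and others not (TAS2R39 at 4.53 against 4.56). With only 4 or 2 nested genes behind them, genomic DNA in that extract (0.0676) and unspliced or read-through RNA of the host genes (0.0379) cannot be told apart, and no biological explanation was tested.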
